A study of Mus musculus with 10 samples.

How the data were processed

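RNA from the livers of 10 mice was measured on 2-colour Agilent mouse arrays (design 014868). Per the labels, 5 livers were wild type (WT) and 5 came from mice lacking the glucagon receptor gene Gcgr (KO). The WT group held 3 males and 2 females, and the KO group 2 males and 3 females. The series describes the livers as coming from separate mice, so each liver was taken as 1 replicate. Per the labels' protocols, total RNA was extracted with a Qiagen lipid tissue kit including an on-column DNase step, and was labelled with Cy5 as cRNA with Agilent's Quick Amp kit. It was hybridised with a Cy3-labelled universal mouse reference RNA from Stratagene on every array. No dyes were swapped, so a dye effect specific to a probe is the same in all livers and leaves the differences between groups.

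Arrays were scanned and extracted with Agilent Feature Extraction, version 10.7 per the submitters' processing notes and 10.7.3.1 per the file headers. Per the file headers, the deposited mean spot signals and local background medians are intensity values on a linear scale, neither background-subtracted nor dye-normalised. The deposited LogRatio is the scanner software's log10 of processed Cy5 over processed Cy3, per the file headers. The processed signals are deposited intensity values that the software had background-subtracted, spatially detrended and dye-normalised, per the file headers. The authors' value table of the series holds log2 ratios of liver over reference, as its values showed when each column was set against its own array. How the authors corrected background and normalised for that table is not given in the sources used here. Its column medians lay between 0.00776 and 0.023. It correlated with the log ratios used here at 0.9994 to 0.9996 across probes, with slopes of 0.998 to 1.

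Each array held 45018 spots, of which 1639 were controls, and 41174 distinct probes, 245 of them spotted more than once. Spots with the scanner's outlier flags (169 to 291 per array) were left out, then the mean signals were corrected with normexp (offset 50) and the log2 ratio of Cy5 over Cy3 was normalised by loess within each array, with control spots at weight 0. Spots of the same probe were averaged. The flags were removed before normexp because of what was seen in the data. On the WT 5 array a few flagged spots with a very bright local background (lowest net Cy3 signal -16030) moved the normexp fit, raising the 5th percentile of its corrected Cy3 signal from 62.6 to 377 when they stayed in. The 5th percentile of corrected Cy5 also moved on KO 3 (70.9 to 92.5) and KO 5 (65.9 to 88.8). The opposite order is among the alternatives. Probes well above background in Cy5 on at least 4 of the 10 arrays were kept (26933 probes). Each gene was represented by its probe with the highest mean Cy5 signal, which left 18919 genes, 63 of them with a missing value. Where a gene chosen by the rule below passed for genotype but another of its probes did not pass with the same sign, this is said beside it. Names were taken from the RefSeq gene table of assembly GRCm38.p6. Of the probes, 23082 were named by accession, 6582 by symbol and 3073 by synonym, and 8437 kept the name in the files. Coordinates are those in the array files, whose header names the older build mm7, and no annotation of that build was used here.

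All fits used limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A gene or list past that threshold is said to have passed, risen or fallen. The main model held genotype and sex, and gave KO minus WT and female minus male. A second model with an interaction gave the KO effect in females (3 KO, 2 WT), in males (2 KO, 3 WT) and the difference between them. Values are mean log2 ratios against the reference ± SD, and log2 fold changes with their standard errors (SE). Gene lists were tested with camera (preset correlation of 0.01) on the main model, adjusted over 36 lists. Camera with an estimated correlation and fry were run beside it. The fry directional test asks whether the members move one way on balance and its mixed test whether they change in either direction, and neither compares a list with other genes.

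The lists were amino acid catabolism, amino acid transport, urea cycle, gluconeogenesis, cAMP and CREB responsive genes, glycolysis and glycogen, fatty acid synthesis, cholesterol synthesis, fatty acid oxidation and ketogenesis, lipoproteins, bile acid synthesis and transport, xenobiotic metabolism, NRF2 targets, ATF4 and amino acid response, unfolded protein response, heat shock proteins, acute phase, interferon response, cell cycle, circadian clock, growth hormone and insulin signalling, mitochondrial respiratory chain, pericentral, periportal, male-biased and female-biased liver genes, and markers of Kupffer cells, endothelial cells, stellate cells, bile duct cells, T, B and NK cells, neutrophils, erythroid cells, adipocytes, pancreatic acinar cells and hepatocytes. Some genes are members of several lists. The model, the lists, the threshold, the rule for named genes and the alternatives, apart from 3 named below, were chosen before the data were examined. The rule named Gcgr first, then the 12 largest rises and the 12 largest falls that passed with the same sign in both sexes and whose name is a gene symbol, up to 4 members of each list with the smallest adjusted p, 4 sex-label genes with the 5 largest sex differences in each direction, and up to 4 genes in each direction for the difference between sexes. A few genes this rule names are not reported here. Other genes named in the text (Pck1, Fasn, Csad, Slc6a9, Khk, Pfkfb1, Plin4, Nfe2l2, Gclc, Shmt2, Gdf15, Sp5, Aldh1a1, Lgr5, Hsd17b6, Mcrip1, Aspscr1, Dcxr, the clock, adipocyte and lipid storage genes, and for sex Ifit3, Igtp, Srebf2, Sqle, Creld2, Sdf2l1, Calr, Pdia6, Prlr, Lepr, Igfbp2, Ghr, Kdr, Fcgr2b, C6, Gstp1, Cux2 and Cyp2b13) were chosen after their values were seen, mainly where a count was small.

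The median net Cy5 signal per array was 58.7 to 134, no probe was saturated, and 53.7% to 72.5% of probes were well above background in Cy5. For array data the number of livers limits the precision. The 10 arrays lay on 4 slides (4, 2, 3 and 1 arrays), scanned on a single day, so slide was tested as a batch. Only slides 1 and 3 held both genotypes. Slide 1 held 2 WT males, 1 KO male and 1 KO female, so its difference within a sex is KO 1 minus the mean of WT 1 and WT 2. Slide 3 held 2 WT females and 1 KO male, so its difference also contains that between the sexes. No pair of livers was near identical (correlations of 0.9469 to 0.9946, with a root mean square log2 difference of at least 0.171).

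The procedure was tested on simulated data with 18856 genes, 50 of them changed at each size. The genotype model recovered 72% of genes changed by 0.5 on the log2 scale, 96% at 1 and 100% at 2 and 4, with 17 false calls. The interaction recovered 10%, 56%, 96% and 100% at these sizes, with 3 false calls. Within females it was 32%, 86%, 98% and 100% (3 false calls), within males 38%, 88%, 100% and 100% (7 false calls), and for sex 66%, 94%, 100% and 100% (15 false calls). A list lowered by 0.3 (-0.3) was called at an adjusted p of 1.48e-36, and none of the 30 lists sharing no gene with it was. The simulated genes varied independently of each other, so this run cannot show how often unchanged lists are called in real livers. Random splits of the real livers, given below, called a median of 10 lists. Alternatives tried were no background subtraction, the scanner's log ratio, the authors' table, median centring, quantile and scale normalisation between arrays, the Cy5 channel alone, 2 other filters on dim probes, every probe tested, a trend with robust moderation, array weights, no sex term, slide as a random or fixed block, the replicate number as a block, stricter thresholds, other list tests and each liver left out in turn. Added after the data were seen were the order of the outlier filter, both male KO livers left out, and a clock index as a covariate. With both male KO livers left out, the genotype term rests on the females alone. The KO females lay on slides 1 and 2 and the WT females on slide 3, so there genotype and slide cannot be told apart.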

Results

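Gene expression was measured in 10 mouse livers, 5 WT and 5 KO for Gcgr, the liver's receptor for the fasting hormone glucagon, to find what changes when this receptor is missing. Each value is a log2 ratio of the liver's RNA (Cy5) over a common reference RNA (Cy3). Median net Cy5 signal was 112 to 134 on slides 1 and 2 and 58.7 to 78.9 on slides 3 and 4. The first principal component held 48.5% of the variance and separated the sexes, with males from -36.05 to -16.39 and females from 13.07 to 33.28. The second held 19.2% and separated the genotypes, with KO livers from -21.38 to -8.907 and WT livers from 3.98 to 25.57.

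**Figure D1:**
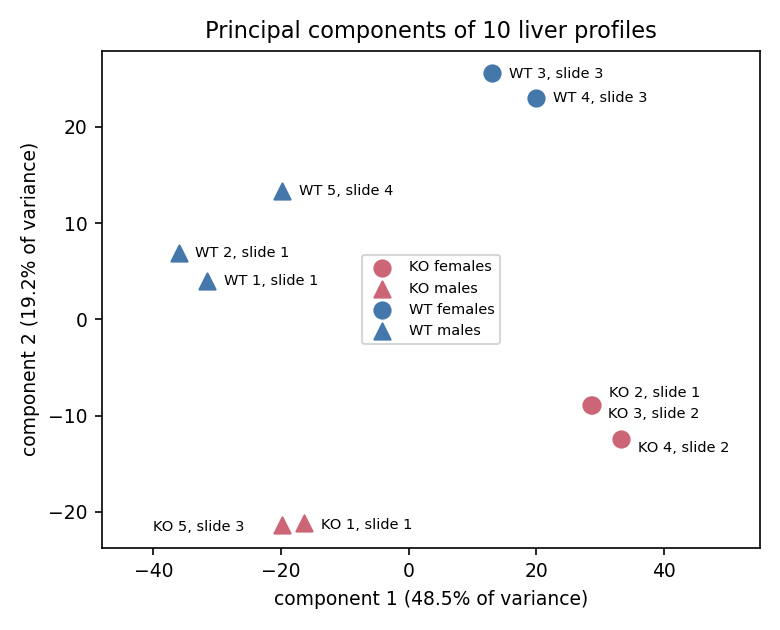
Principal components of the 10 liver profiles, with component 1 (48.5% of variance) on the x axis, component 2 (19.2%) on the y axis and 1 point per liver, coloured by genotype and shaped by sex. All 5 KO livers lie at or below -8.907 on component 2 and all 5 WT livers at or above 3.98.

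Gcgr itself matched the genotype label in every liver. Its log2 ratios were 8.14, 8.09, 7.98, 7.74 and 8.03 in WT livers 1 to 5, and 0.28, 0.36, 0.33, 0.34 and 0.29 in KO livers 1 to 5. The means were 7.99 ± 0.16 (SD, n = 5) and 0.32 ± 0.04 (SD, n = 5), a log2 fold change of -7.66 (SE 0.08, limma adjusted p = 1.1e-13), or 202-fold. The probe lies on chromosome 11 at 120647973 to 120648033 in the coordinates of the array files. The difference was -7.71 with slide as a block, -7.84 within slide 1 and -7.57 within slide 3. The labels do not say which part of the gene was deleted, and the probe remained well above background in all 10 livers.

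After Gcgr, the largest fall was in Nnmt, the enzyme that methylates nicotinamide. Nnmt (chromosome 9, 48564184 to 48564243) went from 4.03 ± 0.48 in WT to -2.22 ± 0.60 in KO livers (SD, n = 5 each), a log2 fold change of -6.23 (SE 0.30, adjusted p = 1.26e-06) or 75-fold. Enzymes of amino acid metabolism were among the other large falls. Oat, ornithine aminotransferase (chromosome 7, 128962937 to 128962996), went from 3.53 ± 0.41 to 0.31 ± 0.22, a fold change of -3.25 (SE 0.18, adjusted p = 3.13e-06). Got1, the cytosolic aspartate aminotransferase (chromosome 19, 43393921 to 43393979), went from 1.34 ± 0.45 to -1.13 ± 0.38, a change of -2.60 (SE 0.13, adjusted p = 1.95e-06). Also among the largest falls were Lrtm1 (-3.43, SE 0.28) and Zap70 (-3.31, SE 0.12), a kinase of T cell receptor signalling. Smaller falls were in the noncoding RNA Meg3 (-2.65, SE 0.31), the sulfotransferase Sult5a1 (-2.33, SE 0.27), the cytochrome P450 gene Cyp2g1 (-1.97, SE 0.29), the lysolipid transporter Mfsd2a (-1.95, SE 0.45), uridine phosphorylase Upp2 (-1.94, SE 0.31) and the amino acid transporter subunit Slc3a1 (-1.91, SE 0.23). The 4 probes of Meg3 ranged from -2.65 to -0.09, and 2 of them passed.

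The largest rise was in the DNA repair gene Rad51b (Rad51l1 in the files, chromosome 12, 77777017 to 77777076). It went from -1.17 ± 0.78 in WT to 2.72 ± 1.21 in KO livers (SD, n = 5 each), a log2 fold change of 3.57 (SE 0.26, adjusted p = 2.48e-05) or 11.8-fold. Rgs16, a regulator of G protein signalling, rose by 3.01 (SE 0.44). Fgf21, a hormone that liver releases in fasting and amino acid stress (chromosome 7, 41790029 to 41790088), rose from -1.11 ± 0.41 to 1.43 ± 0.39, a change of 2.48 (SE 0.20, adjusted p = 6.15e-05) or 5.59-fold. Also among the largest rises were the antimicrobial peptide gene Defb1 (2.43, SE 0.19), the adhesion receptors Adgrv1 (2.37, SE 0.32) and Adgrg2 (1.72, SE 0.10), the homeobox gene Lhx6 (2.27, SE 0.16) and the thyroxine carrier Serpina7 (2.25, SE 0.36). Further rises were in the stress genes Gadd45g (2.18, SE 0.45) and Gadd45b (1.55, SE 0.31), the growth hormone feedback gene Socs2 (1.88, SE 0.45, with 0.44 at a second probe that did not pass) and Id1 (1.55, SE 0.21). A second Lhx6 probe showed no such difference (-0.0018). Defb1 and Adgrg2 were well above background in 1 of 5 WT livers each, and Rad51b and Fgf21 in 4 of 5.

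**Figure D2:**
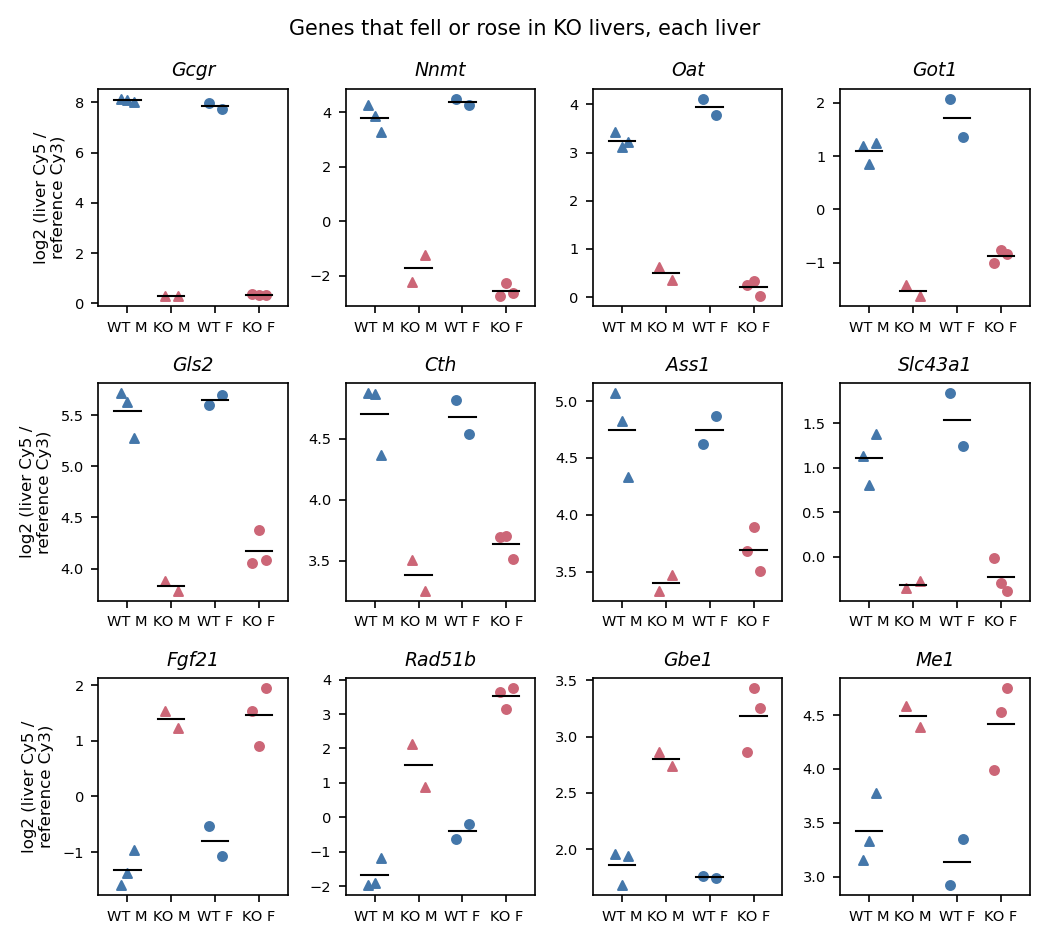
Log2 ratio of liver Cy5 over reference Cy3 (y axes) of 12 genes in each liver, in WT and KO males (triangles) and females (circles), with lines at the group means. In each panel the 5 KO livers lie on one side of the 5 WT livers, for example 0.28 to 0.36 against 7.74 to 8.14 for Gcgr and 0.91 to 1.95 against -1.60 to -0.53 for Fgf21.

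Altogether 1129 of 18919 genes passed for genotype (5.97%), of which 545 rose and 584 fell, and 112 differed at least 2-fold (55 higher, 57 lower). Of all 18919 genes tested, every KO liver lay beyond every WT liver in 1146, where chance gives 0.794% with 5 livers against 5, and 707 of the genes that passed were of this kind. With slide as a fixed block 1202 genes passed (597 rose, 605 fell), 755 of them shared, and 22 of the 24 largest changes still passed. The exceptions were Socs2 (adjusted p = 0.0891) and Mfsd2a (0.122), whose difference within slide 1 was 0.23. Socs2 also failed without any one of KO 1 to KO 5, WT 3, WT 4 or WT 5 (0.0522 to 0.081), Mfsd2a without any one of KO 3, KO 4, KO 5, WT 3, WT 4 or WT 5 (0.0511 to 0.098), and Gadd45g without WT 3 (0.0691). Further calls lost included Upp2 and Serpina7 with the scanner's log ratio, and Cyp2g1 and Gadd45b without the sex term. With outlier spots removed only after the background fit they included Upp2, Slc3a1, Gadd45b and Gadd45g. Upp2 ranged from -2.64 to -0.815 over the alternatives. The count was 595 without WT 3, 597 without KO 1 and 668 without KO 4. With median centring in place of loess 279 genes passed, 72% of them higher, against 48.3% with loess, and with outlier spots removed only after the background fit 338 passed, 58.6% higher.

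Genes that break down amino acids fell together in KO livers. Of 48 measured amino acid catabolism genes 19 fell and 1 rose (29 and 1 adjusted over the list alone). Besides Oat and Got1 they included the glutaminase Gls2 (-1.59, SE 0.10), the cystathionine lyase Cth (-1.18, SE 0.12), the serine dehydratase Sds (-1.44, SE 0.16), the alanine aminotransferase Gpt (-0.60, SE 0.08) and the tyrosine aminotransferase Tat (-0.63, SE 0.11). The one that rose was Csad (0.99, SE 0.14), an enzyme of taurine synthesis. The list passed camera (adjusted p = 2.32e-14, and adjusted p = 0.14 with an estimated correlation). Its median log2 fold change was -0.28, with -0.29 under the slide block, -0.30 within slide 1 and -0.28 within slide 3.

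Amino acid transporters and the urea cycle, which turns amino nitrogen into urea, were also lower. Of 24 transport genes 10 fell and 1 rose (11 and 2 adjusted over the list alone), with Slc3a1 (-1.91), the arginine carrier Slc7a2 (-1.55, SE 0.13), the neutral amino acid carriers Slc43a1 (-1.59, SE 0.14) and Slc38a4 (-0.91, SE 0.10) among the falls and the glycine carrier Slc6a9 (0.60, SE 0.10) as the rise. Slc43a1 was well above background in 4 of 5 KO livers. Of the 8 urea cycle genes 4 fell and none rose (5 and 0 adjusted over the list alone), namely Ass1 (-1.20, SE 0.14), the ornithine carrier Slc25a15 (-0.90, SE 0.13), Asl (-0.53, SE 0.10) and Nags (-0.46, SE 0.08). Over 30 alternatives Ass1 passed in 30, Slc25a15 in 27, Asl in 26 and Nags in 25, its smallest fall being -0.18. Slc25a15 and Asl did not pass without both male KO livers. Both lists passed camera with the preset correlation (adjusted p = 0.00015 and 1.1e-05) and with an estimated one (adjusted p = 0.0456 and 0.0485 with an estimated correlation). The median of the transport list was -0.20, with -0.13 under the slide block, -0.11 within slide 1 and -0.28 within slide 3. That of the urea cycle was -0.40, with the same -0.40 under the slide block, -0.48 within slide 1 and -0.30 within slide 3.

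Genes of glucose production had a smaller median change (-0.09) than the amino acid and urea cycle lists. That difference was not tested, and Got1 (-2.60) is a member. Of 13 gluconeogenesis genes 4 fell and 1 rose (5 and 2 adjusted over the list alone). Got1 and Gpt fell, as did the coactivator gene Ppargc1a (-0.50, SE 0.10, adjusted p = 0.0163, but 0.0512 with slide as a block, with -0.14 within slide 1, and 0.0636 without WT 3) and glucose-6-phosphatase G6pc (-0.37, SE 0.09, adjusted p = 0.0369), while pyruvate carboxylase Pcx rose by 0.37 (SE 0.07, adjusted p = 0.0127). The G6pc call was lost with slide as a block (0.0971) and without any one of WT 1, WT 3, WT 5 or KO 1 to KO 4 (0.0567 to 0.123). Pck1, the enzyme that commits carbon to glucose, had a log2 fold change of -0.67 (SE 0.18, adjusted p = 0.0527). Of 21 genes responsive to cAMP and CREB, the route by which glucagon signals, 4 fell and none rose (7 and 0 adjusted over the list alone), led by the cAMP phosphodiesterase Pde4b (-1.70, SE 0.14, adjusted p = 6.15e-05), with Tat, Ppargc1a and G6pc. The 2 lists passed camera narrowly (adjusted p = 0.0454 and 0.0441, and adjusted p = 0.201 and 0.532 with an estimated correlation) and failed with slide as a block (0.0985 and 0.193). Their medians were -0.09 and -0.11, with -0.20 and -0.05 under the block, -0.14 and -0.13 within slide 1, and -0.17 and -0.03 within slide 3. Gluconeogenesis also failed without any one of WT 1, WT 3, WT 5, KO 3 or KO 4 (0.0525 to 0.0862), and the cAMP list without any one of KO 1 to KO 4, WT 3 or WT 4 (0.0525 to 0.119).

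Several genes of glycogen and sugar use were higher. Of 23 glycolysis and glycogen genes 5 rose and 1 fell (6 and 1 adjusted over the list alone). Among the rises, the glycogen branching enzyme Gbe1 was higher by 1.18 (SE 0.13, adjusted p = 0.000432), Gpi1 by 0.61 (SE 0.14, with -0.0084 at a second probe), pyruvate kinase Pklr by 0.85 (SE 0.20) and fructokinase Khk by 0.52 (SE 0.14), while Pfkfb1 fell (-0.65, SE 0.16). Gpi1 failed without any one of KO 3, WT 3 or WT 4 (0.0516 to 0.0909), and Pklr without any one of WT 2, WT 3, WT 4, KO 3 or KO 4 (0.0569 to 0.103). The list passed camera (adjusted p = 0.00304, and adjusted p = 0.532 with an estimated correlation) but not with slide as a block (0.109). Its median was 0.19, with 0.05 under the block, 0.03 within slide 1 and 0.21 within slide 3.

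Lipid genes were tested as 4 lists. Of 20 fatty acid synthesis genes 3 rose and 1 fell (7 and 1 adjusted over the list alone): the malic enzyme Me1 (1.18, SE 0.16), the desaturase Scd1 (1.24, SE 0.19) and the carboxylase Acacb (0.72, SE 0.19, with 0.15 at a second probe that did not pass) rose, and the desaturase Fads2 fell (-0.73, SE 0.13). Fasn had a change of 0.82 (SE 0.29, adjusted p = 0.131). Of 23 cholesterol synthesis genes 2 fell and none rose (3 and 0 adjusted over the list alone), Hsd17b7 (-0.61, SE 0.10, with -0.33 at a second probe that did not pass) and the mevalonate kinase Mvk (-0.78, SE 0.19). Of 29 genes of fatty acid oxidation and ketogenesis 2 rose and none fell (4 and 0 adjusted over the list alone), Fgf21 and the pantetheinase Vnn1 (1.45, SE 0.25). Of 18 lipoprotein genes 4 rose and none fell (4 and 0 adjusted over the list alone), namely the HDL receptor Scarb1 (0.46, SE 0.07), Apoa4 (1.15, SE 0.25), the phospholipid transfer protein Pltp (1.43, SE 0.32) and Mttp (0.40, SE 0.09), which loads lipid onto particles. The adipocyte marker Cidec, a lipid droplet protein, rose beside these groups by 1.40 (SE 0.34, adjusted p = 0.0372), with the highest values in the 2 male KO livers (3.99 and 3.21, against 0.90 to 1.46 in the other 8).

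In camera the adjusted p of the 4 lipid lists was 0.0346 for fatty acid synthesis, 0.000216 for cholesterol synthesis, 5.63e-05 for fatty acid oxidation and 0.0423 for lipoproteins (adjusted p = 0.782, 0.61, 0.471 and 0.61 with an estimated correlation). Cholesterol synthesis had a median of -0.30, with -0.58 under the slide block, -0.59 within slide 1 and -0.88 within slide 3, and fatty acid oxidation one of 0.21, with 0.19, 0.32 and 0.06. Fatty acid synthesis had a median of 0.26, with 0.07, -0.06 and 0.11, and lipoproteins one of 0.06, with 0.01, 0.01 and 0.00, and these 2 failed with the slide block (0.379 and 0.193). Slide 3 sets a KO male against WT females, so its values also hold sex. The median female minus male difference of cholesterol synthesis was 0.413. Without both male KO livers cholesterol synthesis moved the other way and did not pass (adjusted p = 0.152), nor did fatty acid oxidation (0.18). In that fit genotype rests on the females alone, whose genotypes lay on different slides. Single livers also ended calls: fatty acid synthesis failed without any one of KO 3, KO 4, WT 3 or WT 4 (0.0784 to 0.126), cholesterol synthesis without KO 5 (0.071), and lipoproteins without any one of KO 3, KO 4 or WT 4 (0.0652 to 0.319). Among the genes, Acacb failed without any one of WT 1 to WT 4 or KO 1 to KO 4 (0.0569 to 0.156). Calls were also lost for Mvk without any one of WT 1, WT 2, WT 3, WT 5, KO 1, KO 4 or KO 5 (0.0541 to 0.123), Apoa4 without WT 3 or WT 4 (0.0747 and 0.0594), Pltp without KO 1 or WT 3 (0.0798 and 0.0905), Mttp without any one of KO 1, KO 4, KO 5 or WT 3 (0.0572 to 0.0689), and Cidec without any one of WT 1, WT 2, WT 5, KO 1, KO 2, KO 4 or KO 5 (0.0589 to 0.0942). Without both male KO livers Mvk was at -0.24 (adjusted p = 0.465), Cidec at 0.36 (0.297), Vnn1 at 0.95 (0.112), Fads2 at -0.60 (0.0915), Pltp at 1.65 (0.0756) and Mttp at 0.34 (0.187), none of them passing.

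Targets of NRF2, the regulator of antioxidant genes, were higher. Of 16 measured 6 rose and none fell (8 and 0 adjusted over the list alone), among them Osgin1 (1.36, SE 0.19), Me1, the epoxide hydrolase Ephx1 (0.61, SE 0.10), the glutathione transferase Gstm1 (0.60, SE 0.10; -0.000119 with the Cy5 channel alone), Nfe2l2 itself (0.38, SE 0.09) and Gclc (0.57, SE 0.15). The list passed camera (adjusted p = 3.17e-05, and adjusted p = 0.114 with an estimated correlation), with a median of 0.38 in the main model and under the slide block, 0.41 within slide 1 and 0.44 within slide 3. Of 29 xenobiotic metabolism genes 2 rose (Ephx1 and Gstm1) and none fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.611). Of 21 genes of the ATF4 and amino acid response 4 rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.141, but 0.0258 with slide as a block). The rises were Fgf21, Nupr1 (0.74, SE 0.12), Eif4ebp1 (0.40, SE 0.07, with -0.19 at a second probe) and the glutathione-degrading Chac1 (1.27, SE 0.23), and the falls Shmt2 (-0.39, SE 0.09) and Gdf15 (-0.83, SE 0.22). No member of the unfolded protein response (17 genes, adjusted p = 0.578), the heat shock proteins (12 genes, 0.359, but 0.0107 with slide as a block) or the mitochondrial respiratory chain (25 genes, 0.281) passed, adjusted over all genes or adjusted over the list alone. The respiratory chain passed as lower with the Cy5 channel alone (0.0488) and as higher without both male KO livers (0.00626).

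Of 22 genes of bile acid synthesis and transport 1 rose and 3 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.493). The sterol hydroxylase Cyp8b1 fell (-1.03, SE 0.20), with Hsd3b7 (-0.39, SE 0.09) and Cyp7b1 (-0.49, SE 0.13), and the exporter Abcc3 rose by 0.36 (SE 0.07, with 0.08 at a second probe that did not pass). Of 23 acute phase genes 1 rose and 3 fell (1 and 5 adjusted over the list alone, adjusted p = 0.11), with ceruloplasmin Cp higher by 0.66 (SE 0.07) and the serum amyloid genes Saa1 (-1.62, SE 0.34) and Saa3 (-1.39, SE 0.33) and Orm1 (-0.35, SE 0.09) lower. Of 20 interferon response genes 2 fell and none rose (5 and 0 adjusted over the list alone), Isg15 (-0.52, SE 0.11) and Usp18 (-0.38, SE 0.09). That list passed camera (adjusted p = 0.0394, and adjusted p = 0.61 with an estimated correlation), with a median of -0.13, -0.14 under the slide block (0.193, not passing), -0.09 within slide 1 and -0.50 within slide 3, and it failed without any one of KO 2, KO 3, KO 4 or WT 4 (0.0625 to 0.626). Slide 3 sets a KO male against WT females, and the list's median female minus male difference was 0.475, so the -0.50 also holds sex. Saa1 (0.0503) and Saa3 (0.103) failed with slide as a block. Of these genes Saa1 also failed without KO 1 (0.0646), Saa3 without any one of WT 1, WT 4 or KO 1 to KO 4 (0.0504 to 0.101), and Isg15 without any one of KO 1, KO 4, WT 3 or WT 4 (0.0506 to 0.0855). Calls were also lost for Usp18 without any one of WT 2, WT 3, WT 4 or KO 1 to KO 4 (0.0612 to 0.118), Hsd3b7 without any one of WT 2, WT 3, KO 1, KO 4 or KO 5 (0.0519 to 0.0739), Cyp7b1 without any one of WT 1 to WT 4, KO 1, KO 2 or KO 4 (0.0765 to 0.155), and Orm1 without any one liver other than KO 3 (0.0553 to 0.151).

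Of 21 cell cycle genes 2 rose and none fell (2 and 1 adjusted over the list alone, adjusted p = 0.388), cyclin D1 Ccnd1 by 0.55 (SE 0.12) and the inhibitor Cdkn1a by 0.60 (SE 0.15). Of 19 circadian clock genes 1 fell, the repressor Nr1d1 (-0.47, SE 0.12, adjusted p = 0.044, with 3 probes from -0.47 to -0.05 of which 1 passed), and none rose (1 and 0 adjusted over the list alone, adjusted p = 0.843). The clock list holds genes of opposite phase, so this test of direction cannot show a shift of phase. Of 21 growth hormone and insulin signalling genes 1 rose, Socs2, and 2 fell, Igfbp4 (-0.58, SE 0.09) and Igf1 (-0.35, SE 0.07, with 3 probes from -0.35 to 0.06 of which 1 passed), with 2 and 6 adjusted over the list alone. That list did not pass (adjusted p = 0.62), and its median (-0.01) and test pointed down but its mean (0.16) up. Cdkn1a (0.0701) and Nr1d1 (0.0527) failed with slide as a block. Ccnd1 failed without KO 1 or WT 3 (0.0545 and 0.0807), Cdkn1a without any one of WT 1, WT 3, WT 5 or KO 2 to KO 5 (0.0507 to 0.126), Nr1d1 without any one of WT 1, WT 2, WT 4, WT 5, KO 1, KO 2, KO 4 or KO 5 (0.0567 to 0.126), and Igf1 without WT 3 (0.0578).

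Genes that mark both ends of the liver lobule fell. Of 22 pericentral hepatocyte genes 7 fell and none rose (8 and 1 adjusted over the list alone): Oat, the carriers Slc1a2 (-0.63, SE 0.10) and Slc1a4 (-0.52, SE 0.09), Lect2 (-0.43, SE 0.06), Sp5 (-0.82, SE 0.17), Aldh1a1 (-0.43, SE 0.11) and Lgr5 (-0.69, SE 0.18). Over 30 alternatives Slc1a2 ranged from -1.16 to -0.0184 and passed in 26, Slc1a4 in 27 and Lect2 in 25. Slc1a2 failed with the scanner's log ratio, median centring, scale normalisation and outlier spots removed only after the background fit. Of 20 periportal genes 8 fell and 1 rose (11 and 2 adjusted over the list alone), with Gls2, Sds, Sult5a1 and Ass1 among the falls and Hsd17b6 (0.59, SE 0.13) as the rise. Both lists hold genes of amino acid metabolism named above. They passed camera (adjusted p = 9.48e-06 and 1.16e-06, and adjusted p = 0.0456 and 0.197 with an estimated correlation). The pericentral median was -0.30, with -0.41 under the slide block, -0.31 within slide 1 and -0.56 within slide 3, and the periportal one -0.29, with -0.34, -0.37 and -0.13. Of 19 male-biased liver genes 4 fell and none rose (6 and 0 adjusted over the list alone), led by Susd4 (-1.70, SE 0.12), well above background in 2 of 5 KO livers and not passing without the sex term (0.145), and the list passed (adjusted p = 0.00783, and adjusted p = 0.369 with an estimated correlation). It failed without both male KO livers (0.19), with outlier spots removed only after the background fit (0.299) and with probes above background on all arrays (0.0859). Its median was -0.20, with -0.23 under the block, -0.31 within slide 1 and 1.17 within slide 3, where the KO liver is male and the WT livers female. Of 19 female-biased genes only Abcd2 rose (0.85, SE 0.15, with 0.50 at a second probe that did not pass, and well above background in 2 of 5 WT livers) and none fell (2 and 1 adjusted over the list alone, adjusted p = 0.611, with the median at -0.00104 and the mean at 0.13).

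Of 15 endothelial markers 3 rose and none fell (9 and 0 adjusted over the list alone), Lyve1 by 1.47 (SE 0.25), Oit3 by 0.34 (SE 0.09, with 0.22 at a second probe that did not pass) and Pecam1 by 0.26 (SE 0.07). The list passed camera (adjusted p = 8.89e-06, and adjusted p = 0.197 with an estimated correlation), with a median of 0.23, 0.25 under the slide block, 0.33 within slide 1 and -0.01 within slide 3. Without both male KO livers the list (0.0818) and Lyve1 (1.17, adjusted p = 0.104) did not pass. No marker of Kupffer cells (14 genes) passed, adjusted over all genes or adjusted over the list alone. Of 9 bile duct markers none passed over all genes, and 1 rose and none fell adjusted over the list alone. Both lists passed camera (adjusted p = 0.0482 and 0.0454, and adjusted p = 0.809 and 0.369 with an estimated correlation). Their medians were both 0.23, with 0.18 and 0.09 under the slide block, 0.10 and -0.12 within slide 1, and 0.28 and 0.10 within slide 3. The Kupffer list failed without any one of WT 2, WT 3, WT 5, KO 3, KO 4 or KO 5 (0.0592 to 0.97), and the bile duct list without any one of WT 1, WT 3, WT 4 or KO 2 to KO 4 (0.0525 to 0.137) and with slide as a block (0.0587).

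Among 15 markers of T, B and NK cells Cd79b rose by 0.48 (SE 0.12) and none fell (1 and 0 adjusted over the list alone, adjusted p = 0.697). Of 5 adipocyte markers measured 1 rose, Cidec, and none fell (2 and 0 adjusted over the list alone, adjusted p = 0.181). None passed among markers of stellate cells (15 genes, adjusted p = 0.568), neutrophils (5 genes, 0.62), erythroid cells (4 genes, 0.953), pancreatic acinar cells (11 genes, 0.611) or hepatocytes (10 genes, 0.36), adjusted over all genes or adjusted over the list alone. Cd79b failed without any one of WT 1, WT 2, WT 3, KO 1, KO 2 or KO 4 (0.0548 to 0.0959), Oit3 with slide as a block (0.0992) and without any one liver other than WT 1 or KO 3 (0.0685 to 0.138), and Pecam1 with slide as a block (0.102) and without any one liver other than WT 5 (0.0518 to 0.13).

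In total camera called 18 of the 36 lists, 8 higher and 10 lower, and with an estimated correlation 3 (amino acid transport, urea cycle and pericentral genes). The fry directional test called 9 and its mixed test 23. Camera with the preset correlation called a median of 10 lists when the 10 livers were split at random, against 18 for the real groups. With slide as a fixed block 11 of the 18 were called again in the same direction and 12 with slide as a random block. Without KO 3 or KO 4 the count was 11 in each case.

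**Figure D3:**
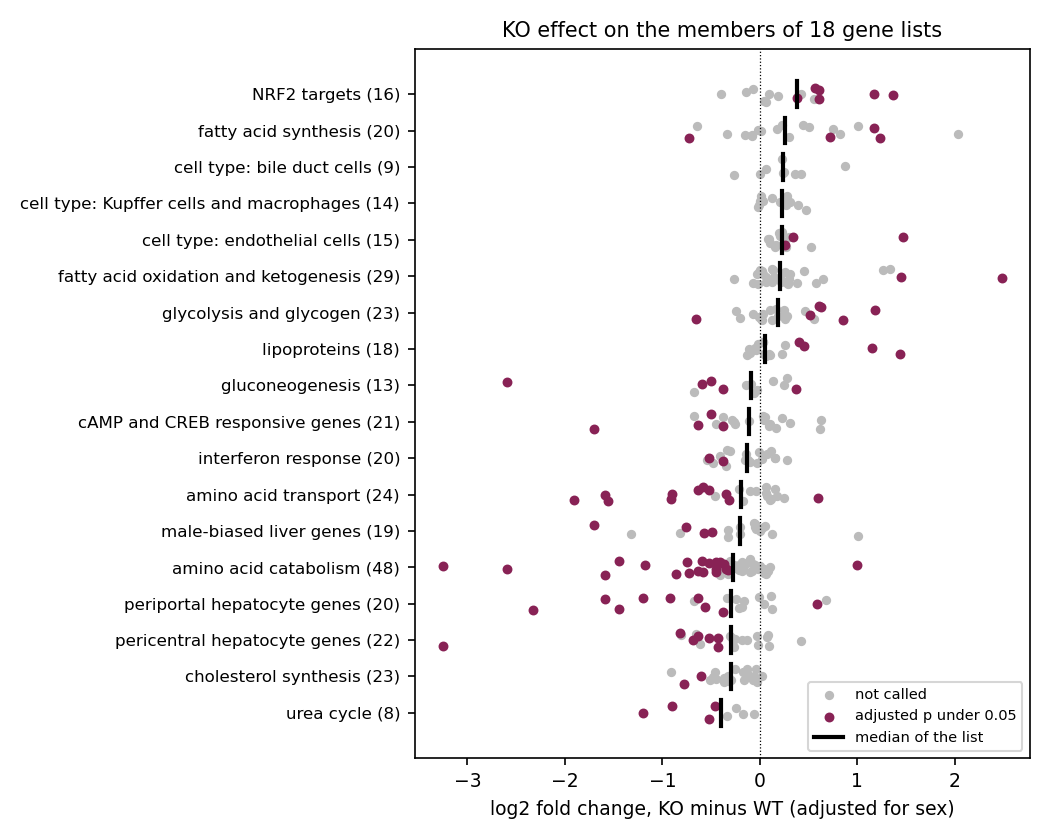
Log2 fold change of KO minus WT livers, adjusted for sex (x axis), of each member of the 18 lists that camera called, with dark points for members that passed at an adjusted p under 0.05, bars at the list medians and the number of measured genes in brackets. Medians ran from -0.40 for the urea cycle to 0.38 for NRF2 targets.

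Whether the KO effect differed between the sexes was tested with the interaction. It passed for 6 genes (2371 at an unadjusted p under 0.05). Cfd, the complement factor also known as adipsin, was higher in KO males by 5.63 (SE 0.43) with -0.0042 (SE 0.43) in females, a difference of -5.64 (SE 0.61, adjusted p = 0.0112). The caveolin gene Cav1 was likewise higher in KO males (3.22, SE 0.20) and not in females (-0.04, SE 0.20), a difference of -3.26 (SE 0.28, adjusted p = 0.00245). The fatty acid elongase Elovl3, a male-biased gene, was higher in KO females by 2.31 (SE 0.12) with -0.29 in males, a difference of 2.60 (SE 0.18, adjusted p = 0.000407). The steroid enzymes Cyp17a1 and Sult1e1 fell in females (-1.46 each, SE 0.12) with -0.03 and -0.06 in males, differences of -1.42 and -1.40 (adjusted p = 0.0239 for both). The transcript AK085462 fell in males (-1.50, SE 0.11) with -0.06 in females, a difference of 1.44 (adjusted p = 0.0112). Cfd was well above background in 4 of the 10 livers, the 2 KO males and 2 WT livers. No KO female was among them, so its value in females and the size of its difference rest on values near the floor.

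**Figure D4:**
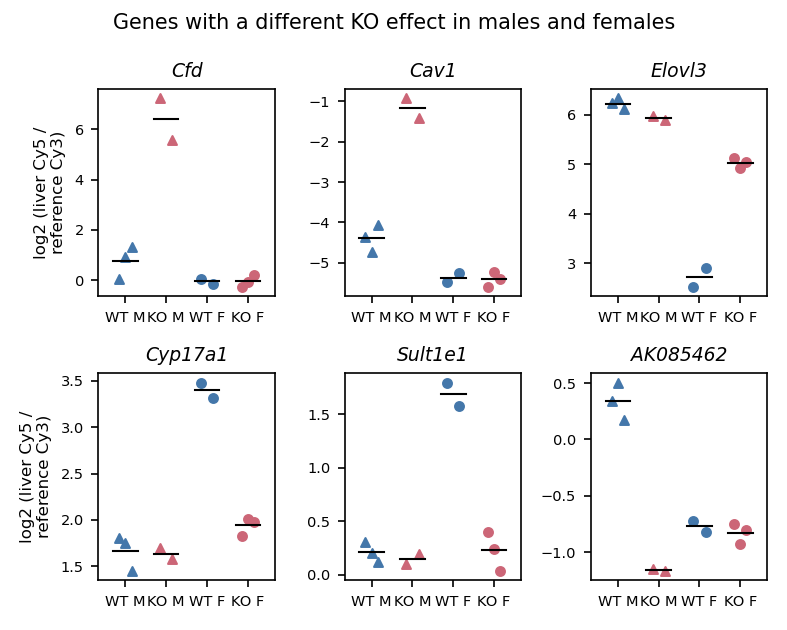
Log2 ratio of liver Cy5 over reference Cy3 (y axes) of the 6 genes with a different KO effect in males (triangles) and females (circles), 1 point per liver, with lines at the group means. Cfd is at 7.22 and 5.56 in the 2 KO males and at or below 1.31 in the other 8 livers, and Elovl3 is at 2.53 and 2.91 in the 2 WT females and at or above 4.92 in the other 8.

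Within the sexes, 839 genes passed in females (429 rose, 410 fell) and 446 in males (227 rose, 219 fell). Both WT females lay on slide 3, with no KO female there, and for Elovl3, Cyp17a1 and Sult1e1 it is the WT females that stand apart (2.53 and 2.91, 3.48 and 3.32, 1.79 and 1.57). Within slide 1 the male difference was 6.74 for Cfd, 3.62 for Cav1 and -1.57 for AK085462, and -0.31, -0.08 and -0.15 for Elovl3, Cyp17a1 and Sult1e1. With slide as a random block 4 genes passed the interaction and 250 passed in females, Cyp17a1 and Sult1e1 no longer being among the 4. The interaction count was 115 without KO 1, 54 without WT 3, 25 without WT 5, 22 without KO 2, 3 without KO 3 and 2 without WT 4. Calls were lost for AK085462 without KO 4 or WT 4 (0.0502 and 0.0861), Cfd without KO 3 or WT 4 (0.0504 and 0.0861), Cyp17a1 without any one of WT 2, WT 4, KO 3, KO 4 or KO 5 (0.0511 to 0.0861) and Sult1e1 without the same livers (0.0539 to 0.107). The female count was 534 without KO 2, 306 without KO 3, 262 without KO 4, 336 without WT 3, 272 without WT 4 and 1277 without WT 5. The male count was 278 without WT 1, 189 without WT 2 and 127 without KO 5.

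More genes differed by sex than by genotype. The X-inactivation RNA Xist was higher in females (6.51, SE 0.19) and the Y-linked genes Eif2s3y (-5.60, SE 0.07), Ddx3y (-4.36, SE 0.19) and Kdm5d (-1.56, SE 0.07) lower, matching the sex label in all 10 livers. The sulfotransferases Sult2a2 (7.36, SE 0.37) and Sult3a1 (6.55, SE 0.21) and the thioesterase Acot3 (3.97, SE 0.22) were higher in females. In males Sult2a2 was well above background in 1 of 5 livers, Sult3a1 in 3 and Acot3 in 4, and in females Kdm5d in 3 and Moxd1 in 4, so these folds rest in part on values near the floor. The acetyltransferase family genes Nat8f5 (-5.14, SE 0.27) and Nat8 (-3.84, SE 0.12), Cml5 and Cml4 in the files, and the monooxygenase Moxd1 (-3.64, SE 0.64) were lower. Where a probe was not well above background in any liver of one sex, the fold is a bound from the Cy5 signals: Xist was at least 76.6-fold higher in females, and Eif2s3y, Nat8f5 and Ddx3y at least 41.6-fold, 32.5-fold and 15.8-fold higher in males.

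For sex 2179 genes passed, 943 higher and 1236 lower in females, and 388 differed at least 2-fold (99 higher, 289 lower). With slide as a fixed block 2110 passed. Of the genes that passed for sex 272 also passed for genotype, where 130 would by independence, both effects coming from the same livers and fit.

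The livers also differed in clock genes. The clock index (Arntl, Npas2 and Clock minus Dbp, Per1 and Per2, log2) was 1.91, 1.96 and 2.1 in the 3 KO females, 0.8 and -0.263 in KO males 1 and 5, 0.625 and 1.26 in WT males 1 and 2, 0.542 and 0.434 in the WT females and 0.00491 in WT 5. With this index as a covariate 1294 genes passed for genotype, 907 of them shared with the 1129, and 12 lists passed. Of the 18 lists, those lost with it were gluconeogenesis (0.0763), cAMP and CREB responsive genes (0.345), glycolysis (0.0779), fatty acid synthesis (0.203), lipoproteins (0.317), interferon response (0.462) and bile duct cells (0.167). The ATF4 and amino acid response (0.0341) was gained. Without both male KO livers 778 genes passed, 454 of them shared. This fit compares KO females with WT females, which lay on different slides. Calls lost or gained in it may thus reflect slide or sex as well as the 2 livers left out. Among genes chosen by the rule that had passed, 58 still did and 30 did not. Of the lists 14 passed. Lost were gluconeogenesis (0.0502), cholesterol synthesis, fatty acid oxidation, male-biased genes, Kupffer cells and endothelial cells. Gained were the respiratory chain and hepatocyte markers (0.0294).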

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

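The tests of adipose tissue and of slide for the male KO pattern were chosen only after that pattern was seen.

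Among 210 groups of 5 livers, 5 had a liver far from the other 4, while chance gives about 1 group in 20. For Lhx6, KO 4 was at 2.72 against 2.13 to 2.28 in the other KO livers, a gap of 0.754 of the group's range. For Adgrg2, WT 4 was at -0.295 against -0.729 to -0.654 (gap 0.827). For Ddx3y, the male WT 5 was at 0.804 against 1.61 to 1.78 in the other males (gap 0.825). For Gls2, WT 5 was at 5.28 against 5.6 to 5.71 (gap 0.743), and for G6pc, KO 5 was at 5.91 against 5.62 to 5.68 (gap 0.816).

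The KO effect differed between the sexes, by the interaction test in limma, for 6 genes. The difference, females minus males, was 2.6 for Elovl3, 1.44 for AK085462, -5.64 for Cfd, -3.26 for Cav1, -1.42 for Cyp17a1 and -1.4 for Sult1e1. WT females, the livers that stand apart for Elovl3, Cyp17a1 and Sult1e1, lay only on slide 3, where no KO female was run, so for females slide and genotype cannot be told apart. The male KO 5 on the same slide was at 5.88 for Elovl3, 1.58 for Cyp17a1 and 0.20 for Sult1e1, near the other males (5.97 to 6.32, 1.45 to 1.80 and 0.10 to 0.30).

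Cfd, Cav1, Cidec and Plin4 were high in both male KO livers: Cfd was at 7.22 and 5.56 against 0.0647 to 1.31 in WT males, Cav1 at -0.924 and -1.4 against -4.73 to -4.06, Cidec at 3.99 and 3.21 against 0.909 to 1.38, and Plin4 at 1.67 and 0.615 against -1.17 to -0.457. A slide effect would reach the other livers of the slide, but for each of the 4 genes, on slides 1 and 3, the male KO liver stood above their mean by at least 0.615 of the KO minus WT difference in males. On slide 1 these others include WT 1 and WT 2, which also enter that difference. On slide 3 they are the WT females, so the gap there also holds sex. The values show only that the slide's other livers did not, on average, share the high level. Adipose tissue carried into the samples would bring its other abundant transcripts and stays open: the median difference of Adipoq, Retn, Plin1 and Lep between KO and WT males was -0.0809 (Retn 0.351, Plin1 -0.221), but the probes of Adipoq and Lep were well above background on 0 arrays in Cy5, and on 1 and 0 in the reference, while Fabp4, another adipocyte transcript, was at 4.52 and 4.34 against 3.46 to 3.75. A lipid storage programme of the type driven by PPARG in male KO hepatocytes may also account for it and stays open: the median of 8 other such genes (0.104, with Cidea at 1.24 and G0s2 at -0.649) lay at the 94.5 percentile of 10000 random lists matched on signal, short of the 95th named in advance. In KO 1 alone Cidea was at 2.51 and G0s2 at 0.307 against the WT male mean, so the 2 male KO livers were unlike for both genes. With only 2 male KO livers, other differences between these mice stay untested.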

How the results depend on the processing

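The tests with the other order of the outlier filter, without both male KO livers and with the clock index were chosen only after results were seen.

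The genotype count was 1129, and moved by over 1.5 times to 279 with median centring, 617 without the sex term, 338 with outlier spots left out only after normexp, 369 at an adjusted p under 0.01 and 112 with at least 2-fold. Leaving out single livers gave 595 (without WT 3) to 1177, with 597 without KO 1 and 668 without KO 4. The sex count (2179) was 914 with median centring, 783 with the later outlier filter, 1049 at 0.01, 388 with at least 2-fold, and 1538 to 2499 without single livers. The count for the difference between the sexes (6) was 1 with the scanner's log ratio, 2 with the Cy5 channel alone, 10 with scale normalisation, 1 with the later outlier filter and 2 (without WT 4) to 115 (without KO 1) without single livers. The female count (839) was 213 with median centring, 250 with slide as a random block, 130 with the later filter and 262 (without KO 4) to 1277 (without WT 5) without single livers. The male count (446) was 104 with median centring, 280 with scale normalisation, 784 with array weights, 58 with the later filter and 127 (without KO 5) to 571 without single livers. The stricter thresholds lower counts by construction. For the others the cause was not tested. With the later filter, the background fits moved on WT 5, KO 3 and KO 5, but whether this lowers the counts was not tested. Where a group was left with 1 liver, that liver was assumed to vary like the others. Quantile normalisation between arrays changed nothing, since it alters only the mean intensities.

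Camera called 18 lists, 3 with an estimated correlation, and fry directionally 9, and 11 (without KO 3 or KO 4) to 18 without single livers. Directions turned for cholesterol synthesis (adjusted p = 0.152) and Kupffer cells (0.821) without both male KO livers, for the mitochondrial respiratory chain with the Cy5 channel alone (0.0488, lower) and for Gstm1 with that channel (-0.000119). The cause was not tested. Over all alternatives, single genes were followed only where chosen by the rule. Those that passed for genotype kept sign and call in 2152 cases, kept only the sign in 480 and turned in 1. Chosen genes that had not passed for genotype did so in 81. The lists that passed kept direction and call in 428 cases, kept only the direction in 128 and turned in 2. Chosen genes of the difference between the sexes lost their call in 36 cases, and chosen sex genes kept theirs in 275 and lost it in 1. These cases do not cover the rest of the 1129 genotype genes and 2179 sex genes. Gcgr ranged from -8.87 to -7.21, Nnmt from -6.93 to -5.95, Oat from -3.75 to -3.08, Got1 from -2.74 to -2.46 and Fgf21 from 2.26 to 3.34, and these 5 passed under every alternative run for them. Signal over background limits the fold of dim probes, such as Cfd (well above it in 4 of 10 livers) and Defb1 and Adgrg2 (in 1 of 5 WT livers each), and net Cy5 signal was lower on slides 3 and 4 (58.7 to 78.9) than on slides 1 and 2 (112 to 134).

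Whether the replicate numbers pair WT and KO livers could not be decided. Livers of a number share their sex except for number 2. Residuals of same-numbered livers after removing genotype and sex correlated at -0.22, 0.251, -0.306, -0.277 and -0.16. No WT liver correlated best with the KO liver of its number. Removing both terms itself pushes residuals of WT and KO livers of the same sex towards negative correlation, so these values leave pairing open. With the replicate number as a block the genotype count was 302 with sex and 455 without it, the sex count was 139, and 17 and 13 lists passed. With the block and sex in the model, the sex effect rests on the single pair of number 2 and the genotype effect on the other pairs. This and the fewer degrees of freedom lower the precision. Other causes were not tested.

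The 10 livers were split into 5 and 5 in 100 ways, drawn with the real one included. Only the real split gave as many genotype genes (1129, highest other 3), and only the real one as many sex genes (2179, highest other 5). The smallest share such a draw can give is 1 of 100, and the splits were not balanced over slides. The real genotype or sex difference also adds to the spread within the other splits. A chance origin of counts this high is thus made unlikely, but not excluded. At least as many lists (18) came from 2 of 100, the real split included. The other reached 19 and placed 8 of the 10 livers as in the real split. The median split called 10. Such a number of lists was thus rare in these splits, but chance is not excluded for it. For single lists, splits with a camera p as small as the real one were counted, the real split included. The count was 1, the real split alone, for amino acid catabolism and transport. For catabolism another split came nearly as low, while for transport none came as near. The count was 2 for urea cycle, gluconeogenesis, pericentral and periportal genes, where another split went lower than the real one, and 4 for NRF2 targets. It was 7 for endothelial cells, 15 for male-biased genes, 17 for cAMP and for glycolysis, 19 for lipoproteins, 20 for fatty acid oxidation, 21 for bile duct, 36 for interferon, 38 for fatty acid and cholesterol synthesis and 61 for Kupffer cells.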

Other observations

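The list tests by sex, the test of Cy5 signal for the clock genes and the clock index as a covariate were tests chosen only after results were seen.

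Genes of groups other than the sex-biased ones also differed by sex. The list calls here need caution, since camera with the preset correlation called a median of 10 lists in random splits for genotype. No such splits were run for the sex lists. Of 20 interferon response genes 11 were higher in females and none lower (14 and 0 adjusted over the list alone), among them Ifit3 (0.82, SE 0.07, limma adjusted p = 4.48e-05), Ifit1 (1.09, SE 0.15) and the GTPase Igtp (1.55, SE 0.27). The list passed camera (adjusted p = 1.32e-10, and adjusted p = 0.163 with an estimated correlation). Of 23 cholesterol synthesis genes 5 were higher in females and none lower (7 and 0 adjusted over the list alone), among them the regulator Srebf2 (0.66, SE 0.11), Hsd17b7 (0.48, SE 0.10) and Sqle (0.74, SE 0.20), with adjusted p = 4.61e-06, and adjusted p = 0.635 with an estimated correlation. Of 17 unfolded protein response genes 5 were lower in females and none higher (5 and 0 adjusted over the list alone), Creld2 (-0.78, SE 0.13), Sdf2l1 (-0.77, SE 0.13), Hyou1 (-0.53, SE 0.13), Calr (-0.45, SE 0.12) and Pdia6 (-0.32, SE 0.09), with adjusted p = 0.000366, and adjusted p = 0.54 with an estimated correlation. Of 21 growth hormone and insulin signalling genes 3 were higher in females and 1 lower (8 and 1 adjusted over the list alone): the prolactin receptor Prlr (1.59, SE 0.15), the leptin receptor Lepr (1.15, SE 0.16) and Igfbp2 (0.53, SE 0.09) were higher and the growth hormone receptor Ghr (-0.29, SE 0.07) lower, with adjusted p = 0.00121, and adjusted p = 0.06 with an estimated correlation.

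Markers of some cell types differed too. Of 15 endothelial markers 3 were higher in females and none lower (6 and 0 adjusted over the list alone), Kdr (0.43, SE 0.10), Fcgr2b (0.45, SE 0.10) and Oit3 (0.32, SE 0.09), with adjusted p = 0.000529, and adjusted p = 0.443 with an estimated correlation. No Kupffer cell marker passed, adjusted over all genes or over the list alone, while the list did (higher, adjusted p = 0.0349, and adjusted p = 0.758 with an estimated correlation). Of 4 erythroid markers 1, Alas2, was lower (-2.19, SE 0.08) and none higher (1 and 0 adjusted over the list alone), with adjusted p = 0.0411, and adjusted p = 0.253 with an estimated correlation.

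Of 19 male-biased genes 15 were lower in females and none higher (17 and 0 adjusted over the list alone), among them the complement gene C6 (-3.19, SE 0.12), Gstp1 (-3.15, SE 0.25) and Susd4 (-2.50, SE 0.12), with adjusted p = 1.37e-19, and adjusted p = 0.0213 with an estimated correlation. Of 19 female-biased genes 14 were higher and none lower (15 and 0 adjusted over the list alone), among them the transcription factor Cux2 (2.86, SE 0.15) and Cyp2b13 (3.51, SE 0.31), with adjusted p = 2.24e-19, and adjusted p = 0.06 with an estimated correlation.

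Clock genes differed between slides 1 and 2 and slides 3 and 4. Males of the same genotype were compared across slides, KO 5 with KO 1 and WT 5 with WT 1 and WT 2. In this comparison Arntl differed by -1.22 and -0.64 and Per1 by 1.11 and 1. If livers of slides 3 and 4 were collected at another time of day, 8 further clock genes should move with their phase, at least 13 of 16 differences being named in advance, and 14 did. Clock, 1 of the 8, is also in the clock index, and without it 12 of 14 did. Lower Cy5 signal on those slides would move both phases alike, but over these 8 genes their mean shifts differed by at least 0.648, against 0.401 between WT 1 and WT 2. Each comparison has a single liver in an arm and clock genes move together within a liver, so these values leave both a shared time of collection and the signal open. The count for genotype with a clock index as a covariate was 1294, with 907 genes shared.

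Genes near Gcgr on chromosome 11 could carry DNA of the strain in which the gene was targeted. Within 20 Mb of Gcgr 31 of 386 tested genes passed for genotype (8.03%), against 5.93% elsewhere in the genome and 5.6% on the rest of chromosome 11. The excess did not pass (odds ratio 1.38, Fisher's exact test, two-sided p = 0.102), and a small share of such genes stays open. G6pc, Nags, Pecam1 and Cd79b, named above, are among the 31, with probes starting -19161301 to -13857857 bases from that of Gcgr. The nearest of the 31 were Mcrip1 (-0.40, at 4379 bases), Aspscr1 (-0.35, at 163621) and Dcxr (-0.63, at 187215), all lower in KO livers. Whether donor DNA lies behind these was not tested.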
